A study of Mus musculus with 15 samples.

How the data were processed

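Total RNA of 2 placentas per mother was pooled, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, 15 in all, with 5 arrays in each of the control, restricted and leptin groups. Each array stands for a different mother per the labels, and replicate numbers are not shared between groups, so no pairing was used. Per the file headers, Agilent Feature Extraction 9.5.3.1 turned each scan into 1 intensity per spot, the processed signal, which is background-subtracted, spatially detrended and given a surrogate value near background, with no scaling between arrays. The table of processed values that the authors deposited holds a linear ratio with 2 decimals. Its scale was worked out by setting each column against the scanner values: it is the processed signal over the array's 75th percentile, without log or centring between genes, and column medians ranged from 0.07 to 0.11. There 12 columns matched the scanner file of their own sample, while the columns of leptin 21, 23 and 25 matched the scanner files of leptin 23, 25 and 21. All 3 belong to the leptin group, so group comparisons are unaffected, but the replicate numbers of these 3 leptin arrays are those of the scanner files and could be exchanged among them. The authors' test and filters are not given in the sources used here.

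Each array had 44397 spots, of which 43020 were not controls, for 39429 distinct probes. Between 101 and 164 spots per array were marked as outliers and left out, at most 2 spots per array were saturated and kept, and the spots of a probe were averaged; a probe with no spot left on some array was not tested. The main values were log2 of the processed signal minus the array's 75th percentile over non-control probes. The array's accession was matched without its version to the RefSeq table of assembly GRCm38.p6. This named 26055 probes, of which 3358 received another symbol than the one in the file, and 13374 kept the name in the file. Probe coordinates are those of the files, on build mm9 per the file headers. Probes well above background on at least 5 of the 15 arrays were kept (25128), and for the 4247 genes with more than 1 kept probe the one with the highest mean over all arrays was used, which left 20067 genes. Pairwise correlations between arrays ranged from 0.947 to 0.991.

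Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a fit of all 3 groups with 12 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Before the data were examined, 39 gene lists with 881 members were fixed, of which 837 members were tested. They covered trophoblast and other cell types of the placenta and uterus, the Y-linked genes, nutrient transport and metabolism, stress responses, growth, hormone and cytokine signalling. Lists were tested with camera at its preset correlation of 0.01, which asks whether the members moved together relative to the other genes, and again with an estimated correlation and with fry, which asks whether the members move on balance in 1 direction. With the estimated correlation no list passed in any comparison, and with fry 1 list passed, the stromal extracellular matrix in leptin against control (adjusted p = 0.0139). A list mean is the average over its tested members, and its SE and the exact permutation test of it come from the list means of the arrays. The sum of both groups' variances over 5 gave the SE of a list mean, and limma's moderated spread that of a gene.

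Genes were named by a rule fixed at the same time. It took the 12 largest rises and falls among genes past the threshold that carry a gene symbol. Where fewer than 5 passed in a direction, it took the genes with the smallest unadjusted p, up to 5. It took the 4 members with the smallest p of each list that passed, and always Lep, Lepr, Socs3 and the Y-linked genes. A gene not well above background on any array of a group has only a bound there. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background. Correlations between comparisons were set beside 100 simulations without any difference between groups and beside 20 splits of the controls.

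The alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, median centring, no filter on dim probes, probes well above background on all 15 arrays, the mean of a gene's probes, the deposited table (plus 0.01 before log2), slide as a fixed block, only the 2 groups compared, trended and robust variance, array weights, the Y-linked mean as a covariate, other thresholds, and each array left out in turn. Chosen after the data had been seen were slide as a random block (correlation within slides 0.058), the yolk sac marker mean as a covariate, the fits without slide 4 and without the 3 arrays lowest in yolk sac markers, the exact permutation test of list means, and slide as a fixed block together with an estimated correlation. Slide and scan day came from the files. Simulations without a slide effect kept the group means and shuffled the residuals of group and slide over the arrays. On simulated data for restriction against control, with all 20067 genes and 5 arrays per group, the gene test recovered 69 of 100 genes changed by 1 and 51 of 100 changed by 0.585 on the log2 scale with 10 false calls, and the list test called the 1 shifted list and 0 others. The noise was drawn independently for each gene, and each member of the shifted list was lowered by 1 residual SD. Without correlation between genes or a slide effect, these simulations do not show how the list test behaves on the real arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Nothing else was left out except control spots, whose probes have no gene.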

Results

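Gene expression was measured in mouse placentas collected on day 11.5 of pregnancy, with 1-colour Agilent arrays that each held labelled RNA pooled from 2 placentas of 1 Swiss Webster mother. The mothers formed 3 groups of 5. Control mothers ate ad libitum, restricted mothers received 50% of their previous food intake from day 1.5, and leptin mothers were restricted in the same way and given recombinant mouse leptin, the satiety hormone of fat tissue, by injection each day at 1 mg/kg. The 75th percentile of the signal ranged from 917.7 to 1179.4 on control arrays, from 522.2 to 1084.2 on restricted arrays and from 1067.5 to 1666.5 on leptin arrays. Between 55.7% and 69.4% of the probes lay well above background on each of the 15 arrays, and the number of arrays limits the precision of every value below. The arrays lay on 4 slides. Slide 1 held controls 11, 13 and 15 with restricted 9, slide 2 held controls 17 and 19 with leptin 23 and 25, slide 3 held restricted 1, 3, 5 and 7, and slide 4, scanned on the second day, held leptin 21, 27 and 29. The 75th percentile followed the slide, with 522.2 to 985.5 on slide 3 and 1395.8 to 1666.5 on slide 4. On slide 1 restricted 9 (1084.2) lay within the range of the controls (917.7 to 1086.5). On slide 2 the leptin arrays (1067.5 and 1166.0) lay within that of the controls (965.6 to 1179.4). Values are log2 differences of scaled signal with the standard error (SE) and n = 5 arrays per group unless stated. A value with slide as a block rests, for restriction against control, on restricted 9 and the 3 controls of slide 1, and for leptin against control on the 2 arrays per group of slide 2, so the blocked and the within-slide values are identical. The p of a blocked value for restriction assumes that restricted 9 varies like the other arrays, and the p of blocked lists are those at the preset correlation of 0.01, since with slide as a block and an estimated correlation no list passed in any comparison. No slide held both restricted and leptin arrays.

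The tissue makeup of the pools varied widely within groups. The 24 markers of visceral endoderm and yolk sac, the membrane that lies next to the placenta, spanned a 95.5-fold range between array means, from -4.56 on control 11 to 2.02 on control 15 around the mean of all arrays, and leptin 25 (-2.74) and leptin 21 (-2.28) were also low. The group means of this list were -0.18 ± 2.57 in control, 0.75 ± 0.56 in restricted and -0.57 ± 1.85 in leptin (SD, n = 5). Alpha-fetoprotein (Afp), a main secreted protein of yolk sac endoderm, spanned 238-fold. The Y-linked genes, read as a check of the fetal sexes in each pool, were lowest on leptin 23 (-3.84), restricted 1 (-3.18), restricted 7 (-2.41) and control 11 (-2.10), so that low arrays occurred in each group. Ddx3y, Eif2s3y and Uty did not pass in any comparison, and Kdm5d was not well above background on any array.

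The first comparison asked how the placenta of food-restricted mothers differed from that of mothers fed ad libitum. The list of pregnancy-specific glycoproteins, a family of proteins secreted by trophoblast, fell in restricted placentas. Beside the Psg genes it holds related Ceacam genes, and here and below both count as members under that name. Of the 20 measured members 19 were lower, with a list mean of -1.16 ± 0.43 (limma camera adjusted p = 2.97e-15, but adjusted p = 0.458 with an estimated correlation). When adjusted over the list alone, 16 members were lower and 0 higher, against 0 when adjusted over all 20067 genes. Psg19 (probe on chromosome 7, 19375143 to 19375202, build mm9) was 2.93-fold lower (-1.55 ± 0.39, adjusted p = 0.201) and lay below every control on 5 of 5 restricted arrays. Psg16 differed by -1.72 ± 0.44, Psg25 by -1.44 ± 0.39 and Psg26 by -1.36 ± 0.38. The restricted arrays were uneven: the list mean was -1.89 on restricted 5, -0.85 on restricted 7, -0.72 on restricted 3, 0.04 on restricted 9 and 0.49 on restricted 1, against 0.17 to 0.87 on the controls. Restricted 5 also had the most probes well above background (69.4%, against 55.7% to 62.6% on the other restricted arrays). Whether this bears on its low list mean was not tested. In the slide-blocked fit the list mean was -0.44 (adjusted p = 0.0265).

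Markers of spongiotrophoblast and glycogen cells, the trophoblast of the junctional zone, also fell. Of 19 members 14 were lower, with a list mean of -0.48 ± 0.19 (adjusted p = 3.85e-06, and adjusted p = 0.491 with an estimated correlation), and 8 were lower when adjusted over the list alone. Tpbpa, the standard spongiotrophoblast marker, was 1.90-fold lower (-0.93 ± 0.26) and below every control on 5 of 5 arrays. Flt1, a receptor for vascular endothelial growth factor, differed by -0.92 ± 0.21, Pcdh12, a marker of glycogen trophoblast, by -0.52 ± 0.14 and Ncam1 by -0.51 ± 0.12, and none of these genes passed over all genes. Restricted 5 was again the lowest array in this list (-0.83). The list mean with slide as a block was -0.32 (adjusted p = 0.0699), which ends the call.

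Genes of the unfolded protein response, which encode chaperones and folding enzymes of the endoplasmic reticulum, fell as a list. Of 19 members 18 were lower, 4 of them when adjusted over the list alone, with a list mean of -0.19 ± 0.07 (adjusted p = 1.02e-08, and adjusted p = 0.458 with an estimated correlation). Calr differed by -0.32 ± 0.10, Pdia3 by -0.25 ± 0.07, Pdia6 by -0.23 ± 0.07 and Dnajb11 by -0.22 ± 0.07. The 2 probes of Dnajb11 had opposite signs. Restricted 5 was the lowest array in this list too (-0.215). With slide as a block the list mean was -0.09 (adjusted p = 0.0508). Genes of the stromal extracellular matrix fell too, with 18 of 23 members lower, 6 of them when adjusted over the list alone, and a list mean of -0.21 ± 0.08 (adjusted p = 0.000186, and adjusted p = 0.156 with an estimated correlation). Fn1, which encodes fibronectin, differed by -0.45 ± 0.13, Col4a2 and Col4a1, which encode basement membrane collagen, by -0.40 ± 0.12 and -0.36 ± 0.11, and Sparc by -0.33 ± 0.08 on the brighter of 2 probes of opposite sign. The blocked mean of the matrix list was -0.29 (adjusted p = 0.0127).

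The immune cell lists moved in different directions. Markers of uterine natural killer cells, the granzyme-rich lymphocytes of the decidua, rose, with 15 of 16 higher and a list mean of 0.74 ± 0.35 (adjusted p = 0.000361, and adjusted p = 0.765 with an estimated correlation). No member passed when adjusted over the list alone. Gzmf differed by 0.81 ± 0.34 and Gzmd by 0.66 ± 0.31 (0.50 and 0.39 without control 15), Klre1 by 1.00 ± 0.45 (0.65 without restricted 7), and Klrb1c, not well above background on any control, was at least 1.60-fold higher (adjusted p = 0.339). Blocking on slide gave a list mean of 0.87 (adjusted p = 0.000426). Interferon response genes fell, with 25 of 27 lower and a list mean of -0.23 ± 0.26 (adjusted p = 3.65e-05, and adjusted p = 0.765 with an estimated correlation). The interferon mean was -0.08 without control 11 (adjusted p = 0.0276), -0.15 without control 17, -0.14 without restricted 1 and -0.39 without control 19. Rsad2, an antiviral enzyme, was 1.44-fold lower (-0.53 ± 0.10, adjusted p = 0.167) and below every control on 5 of 5 arrays, and it was the 1 member lower when adjusted over the list alone. Ddx58 differed by -0.31 ± 0.10, Oas1a by -0.28 ± 0.09 and Stat2 by -0.34 ± 0.13. For interferon the blocked list mean was -0.49 (adjusted p = 2.69e-05). Macrophage markers fell, with 13 of 16 lower and a list mean of -0.21 ± 0.20 (adjusted p = 0.0233, and adjusted p = 0.765 with an estimated correlation; -0.55 with slide as a block, adjusted p = 0.000384). Adgre1 differed by -0.60 ± 0.19 (0.12 with normexp background correction), Csf1r by -0.23 ± 0.12, C1qa by -0.29 ± 0.17 (-0.16 without control 11, -0.46 without control 19) and Lyz2 by -0.55 ± 0.34, and 0 members passed over the list alone. The macrophage call ended without control 11 (list mean -0.11, adjusted p = 0.170), control 15 (0.0574), control 17 (0.0786), restricted 1 (0.0812) or restricted 9 (0.119), and the mean was -0.34 without control 19. The call also ended with normexp (-0.04, adjusted p = 0.134) and with array weights (-0.12, adjusted p = 0.216). Decidua markers, which stand for the maternal tissue around the placenta, had a list mean of 0.09 ± 0.34 and were not called.

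5 further lists passed with small shifts. Genes of oxidative phosphorylation rose relative to other genes, with 35 of 41 higher and a list mean of 0.11 ± 0.04 (adjusted p = 0.000405, and 0.765 with an estimated correlation), although the list mean was -0.09 with normexp background correction and -0.03 with median centring. Cytosolic ribosomal protein genes had 37 of 40 higher and a list mean of 0.14 ± 0.07 (adjusted p = 1.97e-05, and 0.765 with an estimated correlation), which became -0.10 with normexp, -0.01 with median centring and -0.05 with slide as a block. Proliferation genes had 31 of 33 higher and a list mean of 0.18 ± 0.10 (adjusted p = 0.000394, and 0.765 with an estimated correlation; 0.18 with slide as a block, adjusted p = 0.00347), and with normexp their mean of 0.10 lay below the median of all genes, which was 0.16. Cox6c, a subunit of cytochrome oxidase, differed by 0.40 ± 0.13, Rps3 by 0.34 ± 0.13 (-0.10 with slide as a block) and Cdc6, which licenses DNA replication, by 0.53 ± 0.21. Genes of leptin and cytokine receptor signalling fell, with 21 of 27 lower and a list mean of -0.12 ± 0.09 (adjusted p = 0.00433, and 0.634 with an estimated correlation; -0.15 with slide as a block, adjusted p = 0.127). Stat5a differed by -0.34 ± 0.10 (0.16 with normexp), Cish, a cytokine-induced inhibitor of this pathway, by -0.28 ± 0.12, and the receptor subunits Il6st and Lifr by -0.50 ± 0.22 (-0.29 without control 11) and -0.50 ± 0.21. Autophagy and FoxO target genes had 15 of 26 lower and a list mean of -0.06 ± 0.10 (adjusted p = 0.0270, and 0.765 with an estimated correlation; -0.05 with slide as a block, adjusted p = 0.638), with Cited2 at -0.27 ± 0.10, Fbxo32 at -0.27 ± 0.11, Irs2 at -0.31 ± 0.14 (0.08 with slide as a block) and Ulk2 at -0.25 ± 0.09. No member of the 5 lists passed over the list alone. Without control 11 the calls of proliferation (list mean 0.10, adjusted p = 0.0792), leptin and cytokine receptor signalling (-0.05, 0.161) and autophagy (0.404, list mean 0.01) ended. The autophagy call also ended without control 17 (-0.03, 0.106), restricted 1 (-0.03, 0.0791) or restricted 5 (0.0756), and its mean was -0.11 without control 15 or 19. The leptin and cytokine mean was -0.19 without control 19. Oxidative phosphorylation had a blocked mean of 0.07 (adjusted p = 0.0486).

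No single gene passed in the limma test of restriction against control at an adjusted p of 0.05 or at 0.10, while 2589 genes had an unadjusted p under 0.05, against 1003 expected by chance, and the smallest adjusted p was 0.167. The lowest unadjusted p among genes with a symbol that were lower belonged to Hdac4, a histone deacetylase (-0.55 ± 0.08), Cd83, an immune cell surface protein (-0.82 ± 0.13), Fam110b (-0.56 ± 0.09), Cacnb3 (-0.52 ± 0.09) and Adamts15 (-0.85 ± 0.15), each below every control on 5 of 5 arrays. Among genes that were higher they were Rbm3, a cold-inducible RNA-binding protein (0.42 ± 0.07), Pkp3, a desmosomal protein (0.42 ± 0.08), Cdh8 (0.54 ± 0.11), Smco1 (0.90 ± 0.19) and Slc24a5 (0.44 ± 0.10), and all 10 genes had an adjusted p of 0.167. The count was 10 without restricted 9 (6 higher and 4 lower), 2 with slide as a block (both lower) and 1217 with array weights. The 4 other restricted arrays shared slide 3 with no control, so most of this comparison runs between slides. Leptin itself (Lep) was not well above background on any array and was not tested. The leptin receptor (Lepr) differed by -0.38 ± 0.26 (adjusted p = 0.544, and 0.00 with slide as a block), with 3 of 4 probes of 1 sign, and Socs3, a target and inhibitor of leptin signalling, by 0.04 ± 0.12 (adjusted p = 0.916), a sign that turned with normexp (-0.08) and median centring (-0.10). Lepr was uneven among restricted arrays, from -0.13 on restricted 5 to 1.61 on restricted 1, against 0.79 to 1.46 on the controls.

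**Figure D1:**
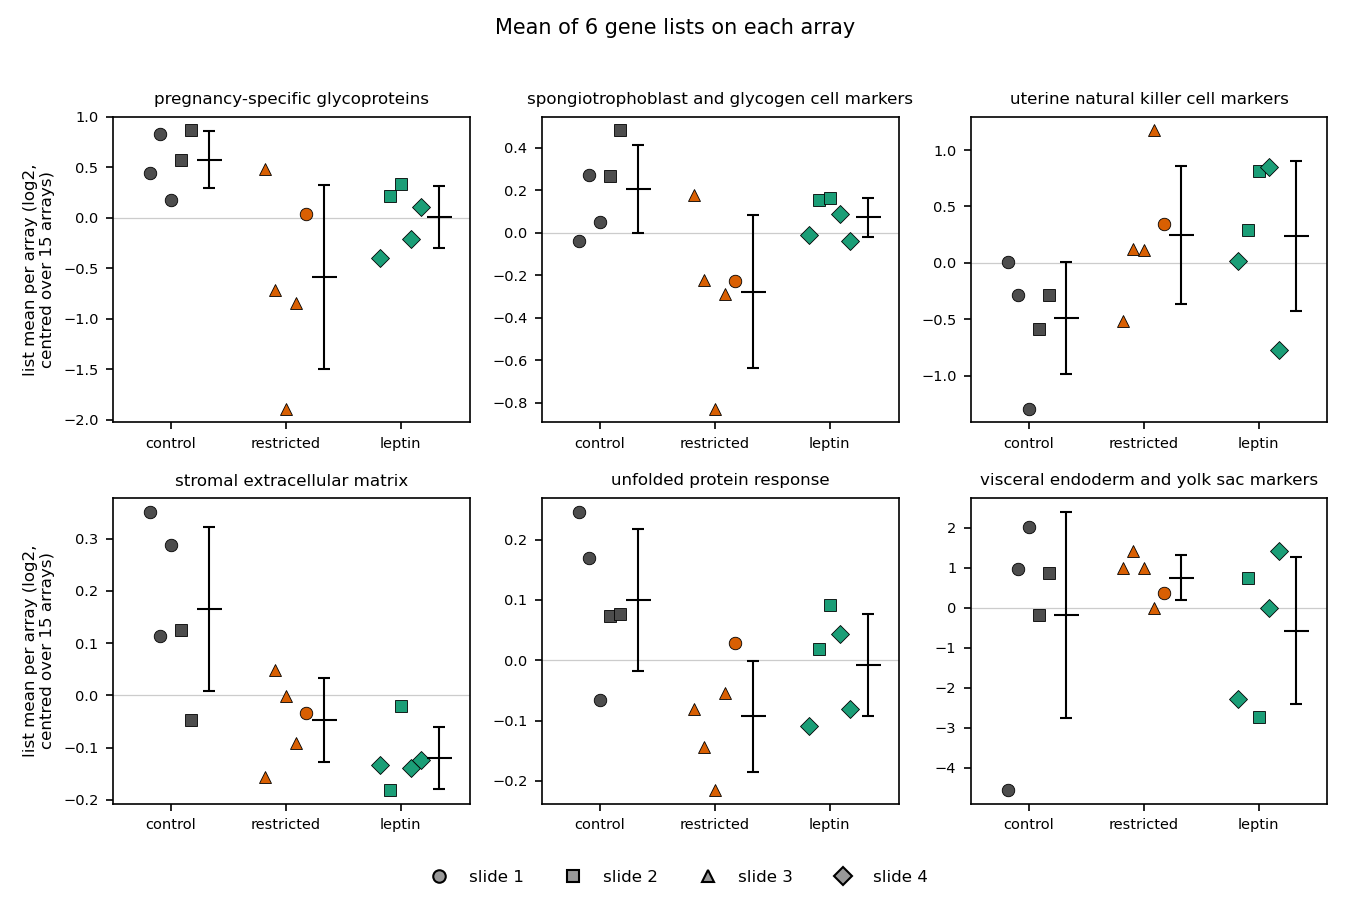
Mean of 6 gene lists on each array (log2, vertical axis, centred over the 15 arrays) by maternal group (horizontal axis), with 1 point per array, marker shape for the slide, and a bar for the group mean ± SD of 5 arrays. The pregnancy-specific glycoproteins reached -1.89 on restricted 5 while restricted 9 and restricted 1 lay at 0.04 and 0.49, and the yolk sac markers ran from -4.56 to 2.02 within the control group.

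The second comparison asked what still differed from ad libitum feeding when restricted mothers received leptin. In limma's test 1074 of 20067 genes passed, of which 707 rose and 367 fell, and 4490 genes had an unadjusted p under 0.05 against 1003 expected by chance. The genes that fell mostly carried a gene symbol (328 of 367), whereas 266 of the 707 that rose did. The largest falls among named genes were those of Slc15a3, a peptide transporter of endosomes and lysosomes (-1.01 ± 0.25), Pkd1, which encodes polycystin-1 (-0.92 ± 0.17), Efna5, an ephrin ligand (-0.82 ± 0.20), Ankrd35 (-0.78 ± 0.20) and Cd83 (-0.77 ± 0.13). Airn, the imprinted transcript antisense to Igf2r, fell by 0.76 ± 0.18 with 3 of 4 probes of 1 sign. Susd2 (-0.75 ± 0.20), Lypd6b (-0.73 ± 0.19), Scarf2, a scavenger receptor (-0.71 ± 0.10), Qsox1, a secreted sulfhydryl oxidase (-0.71 ± 0.18), and Cyp46a1, cholesterol 24-hydroxylase (-0.71 ± 0.19), followed, and Bsn, not well above background on any leptin array, was at least 1.63-fold lower. Cd83 (chromosome 13, 43898276 to 43898335, build mm9), Pkd1 (chromosome 17, 24733161 to 24733220) and Scarf2 (chromosome 16, 17808320 to 17808379) lay below every control on 5 of 5 leptin arrays. With slide as a block these values were -0.72 for Cd83, -0.58 for Pkd1 and -0.47 for Scarf2, and 8 other genes of these 12 stayed below 0, between -0.64 for Lypd6b and -0.26 for Qsox1, with an adjusted p of 1 for each. Bsn, too dim for a value on the leptin arrays, is left out of this range. These falls, and the rises below, were picked as the largest on all arrays, those of slide 2 included. The sign of their blocked values is thus partly built in.

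Among the named genes with the largest rises, Klrb1a, a receptor of natural killer cells, was 4.12-fold higher (2.04 ± 0.52) on 4 of 5 leptin arrays above every control, and 1.95 higher with slide as a block. The others were Sp3, a transcription factor (2.00 ± 0.45), Taf13, a subunit of the general transcription factor TFIID (1.92 ± 0.47), Dph3b (1.80 ± 0.36), Dck, deoxycytidine kinase (1.68 ± 0.41), Ppp5c, a protein phosphatase (1.65 ± 0.39), and Pole4, a subunit of DNA polymerase epsilon (1.61 ± 0.38). These 6 were dim in the control group, where Sp3 and Dph3b were well above background on 1 of 5 arrays, Taf13 and Ppp5c on 2, Dck on 3 and Pole4 on 4, and with slide as a block they were between 0.40 (Dck) and 0.67 (Sp3) higher. Krt86, Sult2a8, Ttc30a2, Nxnl1 and Pex5l were not well above background on any control and were at least 1.90-fold, 1.73-fold, 1.49-fold, 1.40-fold and 1.31-fold higher. The adjusted p of the 24 named genes ranged from 0.0373 to 0.0498. Of the 707 genes that rose, 338 also differed between slides within the groups, against 6 of the 367 that fell and 683 of all 20067. The median signal of the rising genes was -0.87 to -0.78 on the slide 1 controls and -0.22 and -0.06 on the slide 2 controls, 0.03 and 0.15 on the slide 2 leptin arrays and 0.57 to 0.63 on the slide 4 leptin arrays, and restricted 9 on slide 1 (-0.72) lay with its slide. The median of the falling genes was 0.96 to 1.05 on the controls of both slides, 0.70 and 0.73 on the slide 2 leptin arrays and 0.52 to 0.57 on the slide 4 leptin arrays. Both sets were called on these same arrays. A gap between leptin and control arrays with little spread among the controls follows in part from that choice. The medians and the 6 of 367 are therefore no independent test within slide 2. Over 1055 falling genes chosen on slides 4 and 1 alone, the slide 2 leptin arrays scored 0.188, where 1 is the full difference.

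No gene passed with slide as a fixed or random block, with normexp background correction, without the filter on dim probes, in a fit of the 2 groups alone, without slide 4, or without the 3 arrays lowest in yolk sac markers, and median centring left 271 (259 higher and 12 lower). The count was also 0 without control 11, 13 or 15, restricted 3, or leptin 21, 27 or 29, and it was 527 without restricted 1, 1613 without control 19, 4839 with array weights and 1718 with the yolk sac markers as a covariate.

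**Figure D2:**
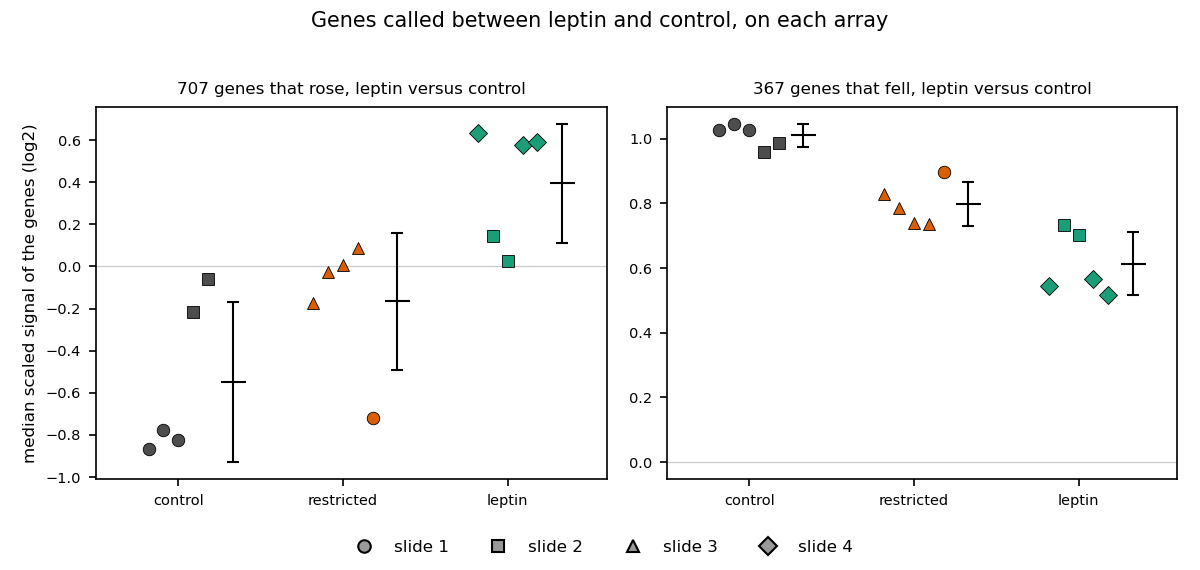
Median scaled signal (log2, vertical axis) on each array of the 707 genes that rose and the 367 that fell in leptin against control, by maternal group (horizontal axis), with marker shape for the slide and a bar for the group mean ± SD of 5 arrays. The rising genes separate the slide 1 controls (-0.87 to -0.78) from the slide 2 controls (-0.22 and -0.06), while the falling genes lie at 0.96 to 1.05 on all 5 controls. Both sets were chosen on these same arrays, so the gap between leptin and control follows in part from the choice.

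5 gene lists passed in leptin against control. Stromal extracellular matrix genes fell, with 19 of 23 lower and a list mean of -0.29 ± 0.08 (adjusted p = 0.00891, and adjusted p = 0.453 with an estimated correlation). Among them Col4a1 fell by 0.47 ± 0.11, Col4a2 by 0.49 ± 0.12 and Sparc by 0.35 ± 0.08 on its brighter probe, though the mean of the 2 Sparc probes was 0.92 higher, and Lum, which encodes lumican, differed by -0.70 ± 0.20 (adjusted p = 0.0555). 3 members passed over all genes and 5 over the list alone. With slide as a block the list mean was -0.14 (adjusted p = 0.0665), which ends the call. Pregnancy-specific glycoproteins fell, with 17 of 20 lower and a list mean of -0.57 ± 0.19 (adjusted p = 0.0177, and adjusted p = 0.986 with an estimated correlation; -0.44 with slide as a block, adjusted p = 0.0267). Psg16 differed by -1.02 ± 0.44, Psg19 by -0.94 ± 0.39, Psg23 by -0.90 ± 0.45 and Ceacam12 by -1.19 ± 0.58 with 2 of 3 probes of 1 sign, and no member passed over the list alone. The call ended without control 19 (adjusted p = 0.0862), leptin 21 (0.0526) or slide 4 (0.238). Uterine natural killer cell markers rose, with 15 of 16 higher and a list mean of 0.73 ± 0.37 (adjusted p = 0.00716, and adjusted p = 0.986 with an estimated correlation; 0.99 with slide as a block, adjusted p = 5.94e-06). Gzmf was 2.33-fold higher (1.22 ± 0.34, adjusted p = 0.0518), the 1 member higher over the list alone, Ncr1 differed by 1.48 ± 0.55, Gzmd by 0.71 ± 0.31 (0.44 without control 15), and Klrb1c was at least 1.97-fold higher (adjusted p = 0.109).

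The other lists that passed in this comparison were oxidative phosphorylation and the interferon response. Oxidative phosphorylation genes rose, with 29 of 41 higher and a list mean of 0.10 ± 0.05 (adjusted p = 0.0242, and adjusted p = 0.986 with an estimated correlation; 0.06 with slide as a block, adjusted p = 0.0571). Uqcrfs1, the Rieske subunit of complex III, rose by 0.35 ± 0.08, Atp5j by 0.35 ± 0.09 and Cox6c by 0.52 ± 0.13, the 3 members past the threshold over all genes, and 4 passed over the list alone. Ndufa8 differed by 0.70 ± 0.21 (adjusted p = 0.0639; 0.00 with slide as a block). This call ended without control 11 (adjusted p = 0.101), control 17 (0.102), leptin 23 (0.196), leptin 29 (0.0523) or slide 4 (0.0985), and with quantile normalization (0.0719), median centring (0.111) or array weights (0.120). Interferon response genes fell, with 24 of 27 lower and a list mean of -0.26 ± 0.25 (adjusted p = 0.0155, and adjusted p = 0.986 with an estimated correlation; -0.03 with slide as a block, adjusted p = 0.621). Rsad2 fell by 0.47 ± 0.10 and Ddx58 by 0.40 ± 0.10, the 2 members past the threshold over all genes and over the list alone, while Bst2 and Stat2 differed by -0.40 ± 0.14 and -0.35 ± 0.13 (0.04 and 0.00 with slide as a block). The interferon call ended without control 11 (list mean -0.11, adjusted p = 0.358), control 17 (0.102), leptin 23 (0.0639) or leptin 29 (0.0523), and the mean was -0.43 without control 19. The lists called for restriction but not here had list means of the same sign. They were -0.13 for spongiotrophoblast and glycogen cells, -0.17 for macrophages, -0.11 for the unfolded protein response and -0.15 for leptin and cytokine receptor signalling. Ribosomal proteins were at 0.09, proliferation at 0.11 and autophagy at -0.03. The smallest camera adjusted p among them was 0.0692, and missing the threshold does not show a list unchanged. Lepr differed by -0.37 ± 0.26 (adjusted p = 0.441) and Socs3 by -0.03 ± 0.12 (adjusted p = 0.933), a value whose sign turned with quantile normalization (0.00) and with slide as a block (0.02).

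The third comparison, leptin against restricted, asked what leptin changed under restriction, and it tests directly whether the restricted groups differed in their distance from control. Pregnancy-specific glycoproteins were the list with the lowest adjusted p and rose with leptin, with 19 of 20 higher and a list mean of 0.60 ± 0.43 (adjusted p = 3.09e-06, and 0.974 with an estimated correlation), less than the spread between the restricted arrays. Psg20 differed by 1.32 ± 0.53, Psg25 by 0.75 ± 0.39, Psg26 by 0.72 ± 0.38 (-0.04 with slide as a block) and Ceacam3 by 0.63 ± 0.23 (-0.28 with normexp). Without restricted 5 Psg20 was 0.84, Psg25 0.33 and Psg26 0.39. Spongiotrophoblast and glycogen cell markers rose, with 17 of 19 higher and a list mean of 0.35 ± 0.17 (adjusted p = 7.28e-06, and 0.974 with an estimated correlation). No single member passed, and those with the lowest p were Phlda2, an imprinted regulator of placental growth (0.70 ± 0.21), Flt1 (0.50 ± 0.21), Car2 (0.39 ± 0.13) and Plac1 (0.29 ± 0.12). Of these, Flt1 and Car2 had a lower mean under restriction than in control, while Phlda2 and Plac1 did not. Phlda2 was 1.13 to 1.99 on restricted arrays and 0.61 to 1.76 on controls, and Plac1 3.69 to 4.01 and 3.59 to 4.11. On leptin arrays Phlda2 was 1.78 to 2.38, above every control, and Plac1 3.88 to 4.42. The rise of Phlda2 was therefore not a return to the control level. Unfolded protein response genes rose, with 16 of 19 higher and a list mean of 0.09 ± 0.06 (adjusted p = 0.00704, and 0.974 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, differed by 0.21 ± 0.08, Pdia3 by 0.20 ± 0.07, Sel1l by 0.17 ± 0.09 and Manf by 0.16 ± 0.08 (-0.15 with slide as a block). Visceral endoderm and yolk sac markers fell, with 23 of 24 lower and a list mean of -1.32 ± 0.86 (adjusted p = 0.0274, and 0.974 with an estimated correlation). None of its members passed, and those with the lowest p were Rbp4 (-1.63 ± 0.92), Apoc2 (-1.76 ± 1.13), Apoa2 (-1.56 ± 1.01) and Slc39a5 (-1.49 ± 0.93), where Rbp4 was -1.04 and Apoc2 -1.13 without leptin 25. Cholesterol synthesis genes fell, with 21 of 24 lower and a list mean of -0.22 ± 0.14 (adjusted p = 0.0268, and 0.974 with an estimated correlation), and the members with the lowest p, which did not pass, were Acat2 at -0.41 ± 0.16, Mvk at -0.31 ± 0.13, Msmo1 at -0.29 ± 0.13 and Dhcr24 at -0.25 ± 0.12. Acat2 and Msmo1 turned with slide as a block (0.15 and 0.36) and Dhcr24 with normexp (0.01). The cholesterol mean moved with the yolk sac markers, to -0.09 (adjusted p = 0.542) with these as a covariate and -0.07 (adjusted p = 0.897) without control 11, leptin 21 and leptin 25, the arrays lowest in them. It was -0.09 (adjusted p = 0.0654) with median centring and -0.14 (adjusted p = 0.386) without slide 4. The cholesterol and yolk sac calls also ended without the filter on dim probes (adjusted p = 0.456 and 0.448), and the yolk sac call with normexp (-1.11, adjusted p = 0.227). With normexp the cholesterol mean of -0.08 lay above the median of all genes, which was -0.17.

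No member of these 5 lists passed over all genes or over the list alone. In the fit with slide as a block, where this difference is the one between the within-slide values of slides 2 and 1, the list means were 0.00 for the pregnancy-specific glycoproteins (adjusted p = 0.759), 0.10 for the spongiotrophoblast and glycogen list (0.570), 0.07 for the unfolded protein response (0.410), -2.21 for the yolk sac markers (0.00331) and 0.06 for cholesterol synthesis (0.410). The yolk sac call ended without restricted 1 (adjusted p = 0.130), restricted 3 (0.137), restricted 5 (0.0825), leptin 21 (0.342) or leptin 25 (list mean -0.78, 0.627), and the cholesterol call without restricted 3 (0.248), restricted 5 (0.0624), restricted 9 (0.0577), leptin 21 (0.137) or leptin 25 (0.438). The unfolded protein response call ended without restricted 5 (list mean 0.06, 0.173) or leptin 25 (0.155). The means of the glycoprotein list and the spongiotrophoblast and glycogen list became 0.27 and 0.21 without restricted 5.

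No single gene passed in the limma test of leptin against restricted, while 2618 genes had an unadjusted p under 0.05 against 1003 expected by chance, and 2 passed at an adjusted p of 0.10, the smallest being 0.0511. The lowest unadjusted p among named genes belonged to Plppr3 (-1.15 ± 0.18, adjusted p = 0.130), Stn1, a telomere maintenance protein (-0.33 ± 0.06, adjusted p = 0.191), Pkp3 (-0.42 ± 0.08), Rad9a, a DNA damage checkpoint protein (-0.44 ± 0.08), and Rnf25 (-0.48 ± 0.09) among lower genes. Among higher genes it belonged to Ciao2b (0.40 ± 0.08), Frmd4a (0.46 ± 0.09, with probes of opposite sign), Gclm, a subunit of the enzyme that begins glutathione synthesis (0.50 ± 0.10), Nkap (0.61 ± 0.13, -0.50 with normexp) and Pcdh17, not well above background on any restricted array and at least 2.09-fold higher, which turned with normexp (-0.32). The adjusted p of the last 8 was 0.224 to 0.229. Without the filter on dim probes 351 genes passed (13 higher and 338 lower), 398 with array weights, 3 without restricted 9, and 1 each without leptin 23 and with quantile normalization. Lepr differed by 0.00 ± 0.26 (adjusted p = 0.999) and Socs3 by -0.07 ± 0.12 (adjusted p = 0.846), values whose signs turned between settings.

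The log2 differences of the restricted and leptin groups from control had Pearson's r = 0.51 across the 20067 genes, which are not independent replicates. Both differences use the same 5 controls, and 100 simulations with no difference between groups gave a median r of 0.54, from -0.24 to 0.91. With the controls split into 2 and 3 arrays, each part serving 1 comparison, the median r over 20 splits was 0.12, from -0.24 to 0.42. The covariance was 0.0591 against a simulated median of 0.0387, a difference of 0.0204, and lay within the simulated range of -0.0155 to 0.212. With split controls its median over 10 splits was 0.0152, from -0.0582 to 0.0559. No gene passed in both comparisons, because none passed for restriction, where 0 are expected of independent lists and the simulations reached 1030. The count was 5 without restricted 9 and 836 with array weights. With slide as a block r was 0.16, and with normexp it was 0.04.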

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

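The 6 counts of other splits and the 2 scores of held-out slides were planned, while the slide tests of the rising and of the falling genes with their simulations, the pseudogene test, both yolk sac tests and both tests of the pregnancy-specific glycoproteins were chosen only after the result was seen, and the bounds for the slide score of leptin against control, for the falling genes and for the share of junctional zone tissue were made stricter afterwards.

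Some single arrays lay far from the other 4 of their group, by a gap to the nearest of over 0.71 of the group's range. This was so in 20 of 384 groups of 5 examined, where chance gives about 1 in 20, or 19. Control 11 had 60.4% of its probes well above background, against 62.4% to 63.2% on the other controls. Among list means, leptin 23 was low in Y-linked genes (-3.84, others 0.30 to 1.70), and restricted 1 in glucocorticoid targets (-0.39, others 0.06 to 0.15) and in steroid synthesis and metabolism (-0.35, others -0.04 to 0.08).

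16 of the named genes also had such an array. Control 15 stood out in Airn (1.45, others 0.52 to 0.75), Efna5 (-1.28, others -2.39 to -2.14), Gzmf (2.21, others 3.61 to 3.97), Klrb1a (-6.65, others -5.12 to -4.51), Ncr1 (-6.18, others -5.15 to -4.88) and Stat5a (-2.09, others -1.85 to -1.80). Leptin 23 stood out in Ddx3y (-6.48, others -0.73 to 0.96), Eif2s3y (-7.31, others -3.05 to -1.44) and Msmo1 (2.52, others 2.26 to 2.30), and leptin 25 in Cd83 (0.22, others -0.16 to -0.07) and Ppp5c (-4.51, others -3.70 to -3.52). The others were Il6st on control 11 (3.45, others 2.17 to 2.49), Cited2 on restricted 5 (5.05, others 5.25 to 5.33), Sel1l on restricted 7 (0.62, others 0.84 to 0.91), Smco1 on restricted 9 (-4.40, others -3.90 to -3.81) and Sparc on restricted 1 (6.46, others 6.66 to 6.74).

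Leptin and restricted placentas, both set against the same controls, differed in 5 gene lists when compared directly with camera at its preset correlation. The list means, leptin minus restricted, were 0.60 for the pregnancy-specific glycoproteins, 0.35 for spongiotrophoblast and glycogen cell markers, 0.085 for the unfolded protein response, -1.32 for visceral endoderm and yolk sac markers and -0.22 for cholesterol synthesis. With an estimated correlation 0 of these lists passed.

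The first pattern weighed is the 1074 genes of leptin against control. 3 of 100 splits of these 10 arrays gave as many, the real one included, so a count this large was uncommon among them. Yet 1 split gave 1622 (controls 11 and 17 with leptin 21, 25 and 27, the 5 of these arrays lowest in yolk sac markers). Another gave 1218 and kept the 3 slide 1 arrays together (controls 11, 13, 15 and 17 with leptin 25). Both point to a structure of the samples, and the slide-blocked count was 0. The splits exchanged arrays without regard to slide or yolk sac content. They therefore cannot exclude a chance alignment of the groups with such a structure. On a scale from 0 at the controls to 1 at the slide 4 leptin arrays, over 2303 genes chosen on these, the slide 2 leptin arrays scored 0.501 on average (0.51 and 0.492), above the planned bound of 0.5 by less than their spread, so slide and leptin cannot be told apart by this score. For the rising genes slide is a candidate explanation. Over 1591 genes chosen on slides 4 and 1 the leptin arrays of slide 2 scored 0.118 above the controls of slide 2 (0.11 and 0.125). Those controls lay 0.527 from the slide 1 controls, of which the choice of genes on the latter explains a part. In 100 simulations without a slide effect the control score was 0.142 in the median and at most 0.431, and the leptin score 0.378 to 0.925. Both observed scores lay outside these ranges, which argues against leptin alone as the source of the full rise of these genes. Annotated pseudogenes, whose probes may cross-hybridise, made up 13.18% of the 683 genes that differ between slides against 2.1% of the others (odds ratio 7.06, Fisher's exact p = 6.62e-40). That test treats genes as independent, and genes outside the 15805 with an annotated type counted as not pseudogenes, so its p does not measure a slide effect. For the falling genes the leptin score within slide 2 over 1055 genes was 0.188 (0.142 and 0.233), with the slide 2 controls at 0.254 (0.193 to 0.314). Both lay within what 97 simulations without a slide effect gave (-0.178 to 0.646 and -0.099 to 0.933), so slide and treatment cannot be told apart for them. Leptin treatment stays open for the falling genes, and for the rising genes as the source of a part of their rise.

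The second pattern is the spread of the visceral endoderm and yolk sac markers between arrays. Yolk sac tissue left on some placentas is a candidate source: the 24 markers had a median pairwise correlation of 0.976 across the 15 arrays with group means removed, where the 99th percentile of 1000 random lists was 0.156, and Apoa1 spanned 560-fold, Ttr 452-fold and Apob 368-fold from control 11 to control 15, and Alb, not well above background on control 11, at least 130-fold. None of the 24 belongs to another list, and 22 were well above background even on control 11. The first principal component, with 30.2% of the variance, followed this score with r = 0.967. The marker mean ran from -4.56 to 2.02 among the controls alone and from -2.74 to 1.42 among the leptin arrays. This argues against maternal treatment as the source of the spread within groups. An effect of treatment on the group means stays open, since a permutation test of the 3 group means gave p = 0.586, which does not show that the groups were equal.

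The third pattern is the fall of the pregnancy-specific glycoproteins in restricted placentas. Across all arrays this list fell further than the spongiotrophoblast and glycogen list, with which it shares no member, by a difference of -0.679 ± 0.272 (SE, n = 5 arrays per group, exact permutation p = 0.0476). Within slide 1 that difference was -0.124, and the gap between the lists on restricted 9 (0.264) lay among those of the controls (0.126 to 0.554), so a lower share of junctional zone tissue cannot be told apart from other causes while slide is open. Slide likewise cannot be told apart from restriction, since restricted 9, the 1 restricted array on a slide with controls, lay -0.442 from their mean (0.04, against 0.17 to 0.83), and restricted 1 on slide 3 (0.49) lay within their range. Restriction stays among the open explanations.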

How the results depend on the processing

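Slide as a random block, the yolk sac covariate, the fits without slide 4 and without the 3 arrays lowest in yolk sac markers, the exact permutation of list means, and slide as a fixed block together with an estimated correlation were chosen only after the result was seen, and the other alternatives were planned. Unless a reason is given, the cause was not tested.

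For restriction against control, where no gene passed in limma's test and 2589 had an unadjusted p under 0.05, the count was 2 with slide as a fixed block (both lower), 1217 with array weights (620 higher, 597 lower) and 499 with an unadjusted p under 0.05 and a fold of at least 1.5, a looser threshold (313 higher, 186 lower). It ranged from 0 to 10 with 1 array left out, and the 10 were reached without restricted 9. The count of leptin against control, 1074, became 0 with normexp, without the filter on dim probes, with slide as a fixed or random block, with only the 2 groups compared, without slide 4 and without the 3 arrays lowest in yolk sac markers. The fits without slide 4, without the 3 low arrays and with 2 groups use fewer arrays. It was 271 with median centring (259 higher, of which 257 were among the 707, and 12 lower, all among the 367), 4839 with array weights and 1718 with the yolk sac covariate, and these 2 held all 1074 genes, and 2278 at the looser threshold of an adjusted p under 0.10. With 1 array left out, and so with fewer arrays, it ranged from 0 (without control 11, 13 or 15, restricted 3, or leptin 21, 27 or 29) to 1613 (without control 19), and it was 527 without restricted 1. Quantile normalization gave 1129 genes, of which 655 were among the 707 that rose and 307 among the 367 that fell, and the deposited table gave 1135 (693 and 359). For leptin against restricted, with 0 genes in limma's test and 2618 at an unadjusted p under 0.05, the count was 1 with quantile normalization, 351 without the filter on dim probes, 398 with array weights, and 2 and 679 at the looser thresholds of an adjusted p under 0.10 and of an unadjusted p with a fold of at least 1.5. Leaving out 1 array gave 0 to 3, with 3 without restricted 9 and 1 without leptin 23. The array weights were highest for control 13 on slide 1 (3.20) and leptin 27 and 21 on slide 4 (2.12 and 2.10). Arrays that share a slide with controls weighed little, with 0.50 for restricted 9, the lowest, 0.53 for leptin 23 and 0.77 for leptin 25. The larger counts with array weights thus lean on comparisons between slides and give no support apart from slide.

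The 12 lists called for restriction against control became 23 with normexp (1 higher, 22 lower), 22 without the filter on dim probes (3 higher, 19 lower), and 0 with an estimated correlation, with or without slide as a block, with fry and with the exact permutation of list means. The 5 of leptin against control became 9 with slide as a fixed block, 3 with array weights, 1 with fry, and 0 with an estimated correlation, with or without slide as a block, and with exact permutation. The 5 of leptin against restricted became 18 with normexp (all higher), 2 with the yolk sac covariate, 3 without the 3 arrays lowest in yolk sac markers, and 0 with an estimated correlation, with or without slide as a block, with fry and with exact permutation. They ranged from 2 (without restricted 5 or leptin 25) to 6 (without leptin 23) with 1 array left out, and were 3 without restricted 3 or leptin 21. The exact permutation allows few distinct splits with 5 arrays per group. Its lowest possible p would not pass for a single list after adjustment over all lists. Several lists would have to reach that p together, so the 0 calls of the exact permutation say little about any list. The correlation of the 2 responses, 0.51, was 0.041 with normexp, 0.155 with slide as a fixed block and 0.123 with split controls, where the 2 responses share no control. The 0 genes called in both comparisons became 836 with array weights and ranged from 0 to 5 with 1 array left out, the 5 without restricted 9.

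Of the list values under the alternatives, 603 kept their direction relative to the other genes and their side of the threshold, 158 kept that relative direction and lost the call, and 9 turned in it, in 5 lists. Among the 158 the list mean itself crossed 0 in 6 values of 4 lists: with median centring oxidative phosphorylation (-0.031) and ribosomal proteins (-0.006) for restriction, with slide as a fixed block, at either correlation, the pregnancy-specific glycoproteins of leptin against restricted (-0.002), and autophagy for restriction without control 11 (0.01) and without the 3 arrays lowest in yolk sac markers (0.01). Normexp moved the median of all genes to 0.163 for restriction against control (0.037 before) and to -0.172 for leptin against restricted (-0.049 before), and the list test is relative to it. With normexp the restriction values were -0.086 for oxidative phosphorylation, -0.097 for ribosomal proteins and 0.095 for proliferation, and the cholesterol synthesis value of leptin against restricted was -0.082. With slide as a fixed block, at either correlation, ribosomal proteins were at -0.052 for restriction and cholesterol synthesis at 0.057 for leptin against restricted. Without the 3 arrays lowest in yolk sac markers the yolk sac list of leptin against restricted was at -0.031, which follows from the choice of these arrays by the same markers and tests nothing. Other calls also ended with the yolk sac alternatives. With the covariate these were macrophage markers (-0.153, adjusted p = 0.108) and autophagy (adjusted p = 0.422) for restriction, and the unfolded protein response (0.047, adjusted p = 0.151) and cholesterol synthesis (-0.093, adjusted p = 0.542) for leptin against restricted, and the value of the yolk sac list itself is 0 by construction. Without the 3 low arrays they were macrophage markers (-0.113, adjusted p = 0.193), proliferation (0.103, adjusted p = 0.0677), leptin and cytokine receptor signalling (-0.052, adjusted p = 0.124) and autophagy (adjusted p = 0.435) for restriction, the pregnancy-specific glycoproteins of leptin against control (-0.571, adjusted p = 0.0511), and cholesterol synthesis for leptin against restricted (-0.067, adjusted p = 0.897). Autophagy for restriction also lost its call with quantile normalization (-0.086, adjusted p = 0.12) and with median centring (-0.203, adjusted p = 0.0504), oxidative phosphorylation for restriction without the filter on dim probes (adjusted p = 0.0869), and with array weights the matrix (-0.268, adjusted p = 0.0728) and interferon lists (-0.218, adjusted p = 0.076) of leptin against control. Median centring moved the median of all genes to -0.108 for restriction against control, and leaving dim probes in moved it to 0.145 there, to -0.101 for leptin against control and to -0.166 for leptin against restricted.

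Of the values of named genes, 3825 kept their direction and side of the threshold, 530 lost the call, 91 gained it, and 83 turned, in 34 results. Most of the 147 results followed had not passed in the main fit, so the kept values are mostly those of genes never called. The calls lost were 32 each with normexp, without the filter on dim probes, with slide as a fixed or random block, and with only the 2 groups compared. In these settings no gene of leptin against control passed. For restriction against control normexp turned Adgre1 (0.12), Eif2s3y (0.387), Pcna (-0.103), Rpl12 (-0.012), Socs3 (-0.082) and Stat5a (0.162). Slide as a fixed block turned Ddx3y (1.012), Eif2s3y (1.005), Irs2 (0.083), Rpl12 (-0.021), Rpl22 (-0.059), Rps3 (-0.095) and Socs3 (-0.076). The mean of a gene's probes turned Dnajb11 (0.112) and Sparc (0.011), whose probes differ in sign. Uty was -0.055 with quantile normalization, -0.067 with array weights and -0.317 without the 3 arrays lowest in yolk sac markers, Eif2s3y was 0.384 with the Y-linked covariate and Socs3 -0.103 with median centring. With 1 array left out Eif2s3y ranged from -0.971 to 0.459, Socs3 from -0.03 to 0.144 and Uty from -0.317 to 0.648.

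For leptin against control slide as a fixed block turned Bst2 (0.044), Eif2s3y (-2.75), Ndufa8 (-0.002), Socs3 (0.016) and Stat2 (0.004). Socs3 was 0.004 with quantile normalization, 0.08 with array weights, 0.052 without slide 4 and 0.087 without the 3 arrays lowest in yolk sac markers. Eif2s3y was -1.632 without slide 4 and -0.696 without those 3 arrays, Uty 0.075 with the Y-linked covariate, and Sparc 0.916 with the mean of its probes. With 1 array left out Ddx3y ranged from -1.672 to 0.188, Eif2s3y from -0.435 to 1.322, Socs3 from -0.10 to 0.074 and Uty from -0.682 to 0.419.

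In leptin against restricted slide as a fixed block turned Acat2 (0.15), Ddx3y (-5.214), Eif2s3y (-3.755), Lepr (-0.164), Manf (-0.145), Msmo1 (0.358), Psg26 (-0.041) and Socs3 (0.092), and normexp turned Ceacam3 (-0.276), Dhcr24 (0.01), Eif2s3y (-0.259), Nkap (-0.495), Pcdh17 (-0.322) and Socs3 (0.055). Without slide 4 Ddx3y was -1.765, Eif2s3y -1.402 and Socs3 0.01, which was 0.052 with median centring, and Lepr was -0.006 with slide as a random block. With 1 array left out Ddx3y ranged from -0.565 to 1.916, Eif2s3y from -0.154 to 1.552, Lepr from -0.21 to 0.225 and Uty from -0.764 to 0.169. The highest of these values for Ddx3y, Eif2s3y and Uty in both leptin comparisons came without leptin 23, the array lowest in Y-linked signal.

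Signal over background limits the dim genes. Lep and Kdm5d, not well above background on any array, were not tested, and genes dim in a whole group have only bounds.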

Other observations

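The counts of other splits and the slide score of restriction against control were planned, and the tests of the decidua hypothesis were chosen only after the result was seen.

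Other splits of the 10 arrays of a comparison into 5 and 5 were counted in 100 draws, the real one included. For the genes of restriction against control 100 of 100 gave as many as the real 0 of limma's test (2589 at an unadjusted p under 0.05), and the highest other count was 369, for controls 11, 13, 15 and 19 with restricted 9 against the rest. That split keeps the 4 slide 1 arrays together, points to a structure of the samples, and stands beside a slide-blocked count of 2. For the genes of leptin against restricted 100 of 100 gave as many as the real 0 (2618 at an unadjusted p under 0.05), and the highest other was 3. Every split reaches a count of 0, so for these 2 comparisons the counts of genes say nothing about chance. For the lists, 54 of 100 splits gave as many as the 12 called for restriction against control (highest other 20), 92 of 100 as many as the 5 for leptin against control (highest other 22) and 84 of 100 as many as the 5 for leptin against restricted (highest other 18). Chance could not be excluded for these 3 counts of lists.

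Over 10 genes chosen on the slide 3 restricted arrays against the controls, restricted 9 on slide 1 scored 0.006 on a scale from 0 at the controls to 1 at the slide 3 arrays. A single array leaves slide and restriction not separable for these genes.

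25 of the 39 lists were called in none of the 3 comparisons, with a smallest adjusted p of 0.0822 (giant cells) for restriction against control, 0.0692 (fatty acid synthesis) for leptin against control and 0.213 (steroid synthesis) for leptin against restricted. The list means below are those of restricted, then of leptin, each against control. Among cell and tissue markers they were -0.18 and -0.13 for trophoblast giant cells, 0.09 and 0.05 for labyrinth and syncytiotrophoblast, 0.13 and 0.13 for trophoblast progenitors, 0.09 and 0.04 for decidua, 0.36 and 0.14 for neutrophils, -0.02 and -0.12 for endothelium, 0.01 and 0.10 for erythroid cells, -0.10 and -0.07 for uterine smooth muscle, and -0.57 and -0.31 for the Y-linked genes. In nutrient handling they were -0.02 and -0.07 for glucose transport and glycolysis, 0.09 and -0.02 for amino acid transporters, 0.10 and 0.03 for fatty acid uptake and storage, -0.003 and -0.076 for fatty acid oxidation and PPAR targets, and -0.04 and -0.21 for fatty acid synthesis. In stress responses they were 0.03 and -0.07 for the amino acid response and ATF4 targets, 0.07 and 0.09 for heat shock proteins, -0.05 and -0.08 for hypoxia targets, and 0.06 and -0.04 for antioxidant defence. In growth, hormone and other signalling they were -0.01 and -0.02 for glucocorticoid targets, 0.01 and -0.06 for imprinted genes, 0.04 and -0.09 for the insulin-like growth factor axis, -0.04 and -0.14 for angiogenic factors and receptors, -0.06 and -0.06 for the circadian clock, -0.06 and 0.03 for steroid synthesis and metabolism, and -0.003 and 0.033 for immediate early genes.

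With slide as a block, 7 lists that had not passed without it did so in leptin against control, which rests on the 2 arrays per group of slide 2, at camera's preset correlation. Blocked on slide with an estimated correlation, 0 lists passed in any of the 3 comparisons (smallest adjusted p 0.313 for restriction against control, 0.274 for leptin against control and 0.98 for leptin against restricted). The 7 were cytosolic ribosomal proteins (0.13, adjusted p = 1.48e-06), erythroid markers (0.38, adjusted p = 0.00388), proliferation (0.16, adjusted p = 0.00515), yolk sac markers (-1.33, adjusted p = 0.00714), antioxidant defence (0.09, adjusted p = 0.0118), Y-linked genes (-3.05, adjusted p = 0.0136) and giant cell markers (-0.27, adjusted p = 0.0267). Some of these rest on 1 array. The erythroid mean was 0.865 on leptin 25 but -0.377 on leptin 23, against -0.368 and 0.106 on controls 17 and 19, and the yolk sac mean -2.735 and 0.751, against -0.18 and 0.86, so both signs would turn without leptin 25. The Y-linked mean was -3.835 on leptin 23 and 0.298 on leptin 25, against 0.952 and 1.61, and the proliferation mean 0.227 and -0.042, against -0.207 and 0.067. For restriction against control, which rests on restricted 9 alone and borrows its spread from the other arrays, the lists at the preset correlation were labyrinth and syncytiotrophoblast markers (0.23, adjusted p = 0.0127), amino acid transporters (0.18, adjusted p = 0.0139) and heat shock proteins (0.19, adjusted p = 0.0174). For leptin against restricted, the difference of the within-slide values of slides 2 and 1, they were ribosomal proteins (0.18, adjusted p = 7.04e-06), erythroid markers (0.49, adjusted p = 0.000273), interferon response (0.46, adjusted p = 0.00161), macrophage markers (0.51, adjusted p = 0.00331) and Y-linked genes (-4.46, adjusted p = 0.00525).

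A hypothesis is that the interferon response list follows the amount of maternal decidua in each sample. With group means removed, Pearson's r of the interferon and decidua list means over the 15 arrays was 0.923 (Spearman's rho 0.929, permutation p = 1e-05 for each, the smallest that these permutations can give, adjusted p = 4e-05 over 4 lists tried), and r was 0.877 without control 19 and restricted 1, the arrays farthest from the median decidua score, and at least 0.858 with any 2 arrays left out, so decidua content may account for part of the interferon spread. The link cannot be called particular to interferon genes, since only 4 lists were tried and others were spread alike. Glucocorticoid targets, which share no member with the decidua list, were highest on control 11 (0.602) and lowest on control 19 (-0.527). Decidua markers had the same extremes (0.672 and -0.955). So had leptin and cytokine receptor signalling (0.350 and -0.184) and autophagy (0.298 and -0.197), both called for restriction against control. No correlation with decidua was computed for glucocorticoid targets or for these lists. The decidua list holds 0 of the 27 interferon members, and all of its 18 tested members were well above background on every array, with Prl8a2, an abundant prolactin-family gene of decidua, at 7.80 in control, 8.44 in restricted and 7.96 in leptin (scaled log2 signal). The same correlation was 0.821 for macrophage markers (rho 0.854, adjusted p = 0.00034, 0.646 without those 2 arrays), 0.614 for the stromal extracellular matrix (rho 0.389, adjusted p = 0.02, 0.245 without the 2 and 0.206 without controls 11 and 19, so it rests on few arrays) and 0.504 for uterine natural killer cell markers (rho 0.511, adjusted p = 0.055, 0.605 without the 2, and as low as 0.332 without another 2). With the means of both group and slide removed r was 0.969 for interferon, 0.842 for macrophage markers, 0.624 for uterine natural killer cell markers and 0.606 for the matrix.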
